A study of Homo sapiens with 4 samples.

How the data were processed

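Gene expression was measured by spatial transcriptomics (10x Genomics Visium) in 4 human lung sections, 3 labelled sarcoid and 1 labelled healthy. A Visium array captures RNA on a grid of barcoded spots, and each spot covers a small piece of tissue that can hold several cells of different types. The labels describe the tissue both as fresh frozen and as formalin-fixed and paraffin-embedded. Per the labels' protocols, the Visium reagent kit for fixed tissue was used, in which transcripts are read through probes. The matrices held 17943 genes and no gene of the mitochondrial genome, so no mitochondrial share could be given. The design text speaks of patients, but the labels do not say that the 3 sarcoid sections come from separate patients, so p-values measure the spread between these sections only, which may be partly technical.

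The deposited matrices hold whole-number UMI counts per gene and spot, which are counts of distinct captured molecules and were not normalized, per the file headers and their values. Per the submitters' processing notes, the authors used Space Ranger 1.3.0 and the GRCh38 build to make these counts. Other settings, the probe set and any filter on spots are not given in the sources used here. The deposited spot positions were used to find neighbouring spots, and each spot with counts lay under tissue. The image scale factors were not used here. Genes carry the symbols of the deposited feature tables. A reference gene table of assembly GRCh38.p14 held 17394 of the 17933 symbols analysed, and it gave the one gene location that is printed. XIST and the Y-linked genes, 10 genes in all, were left out of every test.

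Counts were summed over all spots of a section, because the section, not the spot, is the replicate. Section totals were 4721399, 23599407 and 4929525 UMIs in the sarcoid sections and 2330755 in the healthy section. Values are given as CPM, computed here as counts per 1000000 UMIs of the summed genes. Counting error is small for abundant genes and large below about 10 UMIs. A gene with 0 UMIs in the healthy section was therefore given a bound computed from a floor of 3 counts, and a gene with 1 to 3 counts there a ratio with an exact 95% Poisson interval. Named genes with at most 3 counts over the 3 marker-high zones together are given by their levels, without a ratio. The interval is also given for named genes with fewer than 10 UMIs in the healthy section. These intervals and bounds cover counting error only.

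Sections were compared with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test with TMM factors, filterByExpr, robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. The SE of an edgeR log2 fold change is its absolute value divided by the square root of the F statistic of the test, an approximation. For a gene with few healthy UMIs it can be smaller than counting error alone, as for TNF between sarcoid and healthy sections. With 1 healthy section, the residual spread comes from the 3 sarcoid sections, and the healthy section is assumed to vary as they do. An exact permutation of the 4 sections could not go below 1 in 4. PSAP, the gene named in the series title, was judged by its unadjusted p, with the adjusted p beside it. It may have been chosen on these samples, so neither its direction nor its unadjusted p is taken as independent evidence.

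Within sections, spots with at least 500 UMIs were scored by the mean of log(1 + counts per 10000 UMIs) over 10 genes of granuloma macrophages fixed before the data were examined: CHIT1, CHI3L1, CYP27B1, GPNMB, SPP1, TREM2, ADAMDEC1, MMP9, ACP5 and MMP12. The highest 10% of spots of each section formed the marker-high zone, their 6 neighbours that were not themselves marker-high formed the rim, and all other scored spots the remote zone. The score is a range divided at a fixed share, not a cell type. Of the scored spots, 7, 140 and 53 in the sarcoid sections and 266 in the healthy section lay within 0.1 of the dividing score. Counts were summed per section and zone and tested in edgeR with the section as a block and separate zone terms for sarcoid and healthy. The 10 score genes were left out of the zone tests. Spots were also clustered within each section by the Leiden method (2000 variable genes without the score genes, 20 principal components, 15 neighbours, resolution 0.8), and clusters are described as regions by their leading genes. No doublet caller was run, because a spot is not a cell.

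Before the data were examined, 34 gene lists were fixed for cell types and processes of the lung. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The mitochondrial list had 0 members among the tested genes. For sarcoid against healthy sections and for marker-high and rim against remote zones, the number of genes passing in each list is given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule fixed in advance: PSAP, the 10 largest rises and the 10 largest falls among genes passing the adjusted threshold in the same direction in all 3 sarcoid sections with at least 20 CPM on the higher side, and the 4 members of each list with the smallest p. Some genes that this rule takes are not reported here. The score genes are given by value only in the zone comparisons. Metallothioneins, haemoglobin genes and immunoglobulin constant regions have near-identical copies, and their counts may be shared between copies.

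The alternatives were DESeq2 1.42.0, RLE factors, no expression filter, only spots with at least 500 UMIs, thinning of every section to one total, equal weight for every spot, other zone shares, scores, UMI minimums and rim widths, a zone taken from clustering, no section block, and leaving out each sarcoid section in turn. The remote zones alone, the sarcoid sections alone, and RLE factors for the zone lists were added after the data were seen, as were the comparison of marker-high with rim zones and its alternatives.

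The tests were tried on simulated counts with 200 genes changed by 2-fold or 4-fold. For sarcoid against healthy, 33.7% of the tested genes changed by 4-fold and 2.13% of those changed by 2-fold were recovered among 13893 genes, with 0 false calls. For marker-high against remote, 100% of the 4-fold and 76.3% of the 2-fold changes were recovered among 11698 genes, with 7 false calls. For rim against remote, 100% and 82.7% were recovered among 11707 genes, with 8 false calls. For the difference between sarcoid and healthy zone effects, 21.4% and 2% were recovered among 11687 genes, with 0 false calls. The T cell list, raised by 2-fold in the simulated section comparison, was called with the preset correlation (adjusted p = 7.17e-06) and missed with the estimated one (adjusted p = 0.981). Raised likewise in the simulated zone comparisons, it was called with the estimated correlation for marker-high against remote (adjusted p = 0.00574) and rim against remote (adjusted p = 0.027), and missed for the difference in zone effects (adjusted p = 0.0647). The simulated genes were drawn independently of each other, so these values do not cover genes that vary together. Python 3 libraries (numpy, scipy, scikit-learn, igraph and matplotlib) were used for the sums, zones, clusters and figures.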

Results

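Spatial transcriptomes of 4 lung sections were compared, 3 from lungs with sarcoidosis, a disease in which macrophages and lymphocytes form granulomas, and 1 from a healthy lung. The sarcoid sections held 660, 1859 and 1051 tissue spots with medians of 4723.5, 11477 and 3770 UMIs per spot. The healthy section held 1642 spots with a median of 1383.5 UMIs, and was the shallowest. The series title names PSAP, which encodes prosaposin, the precursor of the saposins that assist the breakdown of sphingolipids in lysosomes. The first question was which genes differ between sarcoid and healthy lung, and the second which genes differ between spots rich in granuloma macrophage transcripts and the rest of the same section.

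PSAP (ENSG00000197746, chromosome 10 from 71816298 to 71851251 in GRCh38.p14) was among the most abundant transcripts of the sarcoid sections. It reached 2738, 3944 and 4224 CPM in sarcoid sections 1 to 3, a mean of 3635 ± 789 CPM (SD, n = 3), against 1064 CPM in the healthy section. It ranked 17, 12 and 13 among all genes by CPM in these sections and 56 in the healthy section. The log2 fold change was 1.83 ± 0.57 (SE), higher in 3 of 3 sarcoid sections. The edgeR quasi-likelihood test gave an unadjusted p of 0.0215 and an adjusted p of 0.134 over 14257 genes, so PSAP did not pass over all genes. The series title names PSAP, which may have been chosen on these samples. Neither its direction nor its unadjusted p is therefore taken as independent evidence. Without sarcoid section 2 the log2 fold change was 1.74 (unadjusted p = 0.0757), without section 3 it was 1.70 (unadjusted p = 0.0905), and in the remote zones alone it was 1.57 (unadjusted p = 0.11). Without section 1 it was 2.06 (unadjusted p = 0.00225, adjusted p = 0.0487), and DESeq2 gave 1.81 (adjusted p = 1.37e-05), so PSAP passed over all genes in these 2 fits; over all the alternatives the adjusted p ran from 1.37e-05 to 0.434.

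Between sarcoid and healthy sections, genes of the granuloma macrophage list and the chemokine gene CCL19 rose, and genes of the blood vessel list fell (adjusted p = 0.445 with an estimated correlation for both lists). CHIT1, which encodes a chitinase secreted by activated macrophages, averaged 662 ± 183 CPM (SD, n = 3) in sarcoid sections against 7.29 CPM in the healthy section (log2 fold change 6.54 ± 0.63, SE). The gelatinase gene MMP9 averaged 896 ± 140 CPM against 11.2 CPM (6.37 ± 0.54), and CCL19, whose product draws lymphocytes and dendritic cells, 384 ± 150 CPM against 3.86 CPM (6.68 ± 0.76). The healthy value of CCL19 rests on 9 UMIs, which puts its ratio of 99.3 between 52.3 and 217 from counting error alone (95% interval). ACKR1, a chemokine-binding receptor of venules, fell from 459 CPM to 44.2 ± 12.8 CPM (log2 fold change -3.34 ± 0.33). In all, 223 genes were higher and 181 lower in sarcoid at an adjusted p under 0.05 among 14257 genes tested with edgeR.

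Some of the largest rises were of genes barely counted in the healthy section. PLA2G2D, a secreted phospholipase, IQGAP2 and the interferon-induced chemokine CXCL11 had 0 UMIs there, and with the healthy section at its floor of 1.29 CPM they were at least 41.5-fold, 25.5-fold and 19.6-fold higher in sarcoid. Transcripts were read through probes, and alleles that could prevent probe binding were not examined. A count of 0 in the single healthy section therefore need not mean absent expression. The metalloelastase gene MMP12 had 1 healthy UMI and a ratio of 231 (95% interval 41.5 to 9132). SULT1C2 had 1 UMI and a ratio of 142 (25.6 to 5625), TIFAB 1 UMI and a ratio of 87.2 (15.6 to 3444), and ADAMDEC1 2 UMIs and a ratio of 96.4 (26.7 to 796). Among the largest falls, DNASE1L3 went from 732 CPM to 25.2 ± 11.2 CPM, the natriuretic peptide receptor NPR3 from 218 to 12.7 ± 6.61 CPM, and the G protein-coupled oestrogen receptor GPER1 from 253 to 20.2 ± 1.83 CPM. CCDC178, SEC14L3, CSF3, MYRIP, PNMT and ADAMTSL1 also fell, from healthy levels between 23.2 and 60.5 CPM.

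Of the 10 granuloma macrophage genes, 8 rose over all genes and 10 adjusted over the list alone, among them CHI3L1 (log2 fold change 4.53 ± 0.46) and the vitamin D 1-alpha-hydroxylase CYP27B1 (4.36 ± 0.66, with 6 healthy UMIs and a ratio of 19.9, 95% counting interval 9.14 to 54.2). Of 29 lysosome and sphingolipid genes other than PSAP, 4 rose over all genes (CTSK, CTSS, GM2A and GLA, log2 fold changes 3.49, 3.02, 2.57 and 2.20) and 13 adjusted over the list alone. GM2A and GLA take part in glycosphingolipid breakdown, and CTSK and CTSS are cysteine proteases. None of the 14 general macrophage genes passed over all genes and 12 did adjusted over the list alone, with FCER1G at 485 ± 100 against 88 CPM (2.52 ± 0.43, adjusted p = 0.0535). Of the 4 tested genes that sort or bind prosaposin, 0 passed over all genes and 3 adjusted over the list alone, 2 upwards. Of 10 alveolar macrophage and 6 neutrophil genes 0 passed over all genes and 4 of each list adjusted over the list alone. CD36, a scavenger receptor, was the 1 lipid-handling gene of 12 to pass and fell (-1.84 ± 0.27), against 7 higher and 3 lower adjusted over the list alone.

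In the interferon-gamma response list 4 of 16 genes rose over all genes and 15 adjusted over the list alone. Those that rose included PSMB9, a subunit of the immunoproteasome (2.29 ± 0.32), and the guanylate-binding protein gene GBP2, at 173 ± 18.2 CPM against 41.6 CPM (2.10 ± 0.28). HLA-DMB rose among 11 MHC class II genes (2.57 ± 0.39), with 10 passing adjusted over the list alone, and TNF among 12 genes of TNF and interleukin-1 signalling (3.36 ± 0.32, with 9 healthy UMIs and a ratio of 9.98, 95% counting interval 5.26 to 21.8), with 1 adjusted over the list alone. Of 12 T cell genes 0 passed over all genes and 9 adjusted over the list alone (0 and 11 of 12 for T cell activation genes), with TRAC, a T cell receptor constant region, at 213 ± 82 CPM against 33 CPM (2.75 ± 0.59, adjusted p = 0.0788). Of 8 B cell genes BANK1 rose (2.72 ± 0.44) and 6 passed adjusted over the list alone. Of 10 plasma cell genes MZB1 and IGHA1 rose (2.69 ± 0.37 and 4.06 ± 0.60) and 7 passed adjusted over the list alone. Of 8 lymphoid follicle and lymph node genes CCL19, LTB and CCL21 rose and 5 passed adjusted over the list alone. The complement gene C2, the glycolytic gene PFKP and the replication clamp PCNA were the single genes of their lists to rise over all genes (2.38, 1.47 and 1.75), against 5, 3 and 5 adjusted over the list alone. CYP27B1 was the 1 gene of the 6 in the vitamin D and calcium list to rise, with 2 adjusted over the list alone.

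Of 12 blood vessel endothelial genes, ACKR1, VWF and PECAM1 fell over all genes and 8 adjusted over the list alone. VWF, the von Willebrand factor gene, went from 1504 to 244 ± 37.5 CPM (-2.58 ± 0.29) and PECAM1 from 995 to 215 ± 1.88 CPM (-2.16 ± 0.25). MMRN1 fell (-2.87 ± 0.32) and CCL21 rose (2.36 ± 0.30) among 7 lymphatic genes, with 1 higher and 2 lower adjusted over the list alone, a median of 0.27 and a camera test pointing down (adjusted p = 0.527). Over all genes 0 of 8 alveolar type 1, 9 alveolar type 2, 8 smooth muscle and 6 gland and cartilage genes passed, against 5 lower, 2 higher, 2 lower, and 1 higher and 1 lower adjusted over the list alone. AGER, a marker of alveolar type 1 cells, stood at 649 ± 304 against 2670 CPM (adjusted p = 0.0979). ADM, which encodes the vasodilator adrenomedullin, fell in the hypoxia list of 7 genes (-2.28 ± 0.32), with 1 higher and 1 lower adjusted over the list alone. All 11 immediate-early and dissociation stress genes had negative log2 fold changes, of which 0 passed over all genes and 1 adjusted over the list alone, with JUN at 321 ± 169 against 1444 CPM (adjusted p = 0.112). No gene of the fibroblast, mast cell, mesothelial, ciliated, secretory airway or erythrocyte lists passed over all genes or adjusted over the list alone, and sarcoid section 1 alone held a region led by salivary-type gland genes (PIP, PRB3 and PRR4, 40 spots).

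With the preset correlation, camera called 21 of 33 lists, and camera with an estimated correlation and fry called 0. The 21 lists each had an adjusted p of at least 0.445 with an estimated correlation and of at least 0.167 with fry. The gene count was 1674 with DESeq2, 794 with every section thinned to one total, 740 without the expression filter and 700 without sarcoid section 1. It was 0 without sarcoid section 3 (2767 genes at an unadjusted p under 0.05) and 0 in the remote zones alone (2066 at an unadjusted p under 0.05).

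**Figure D1:**
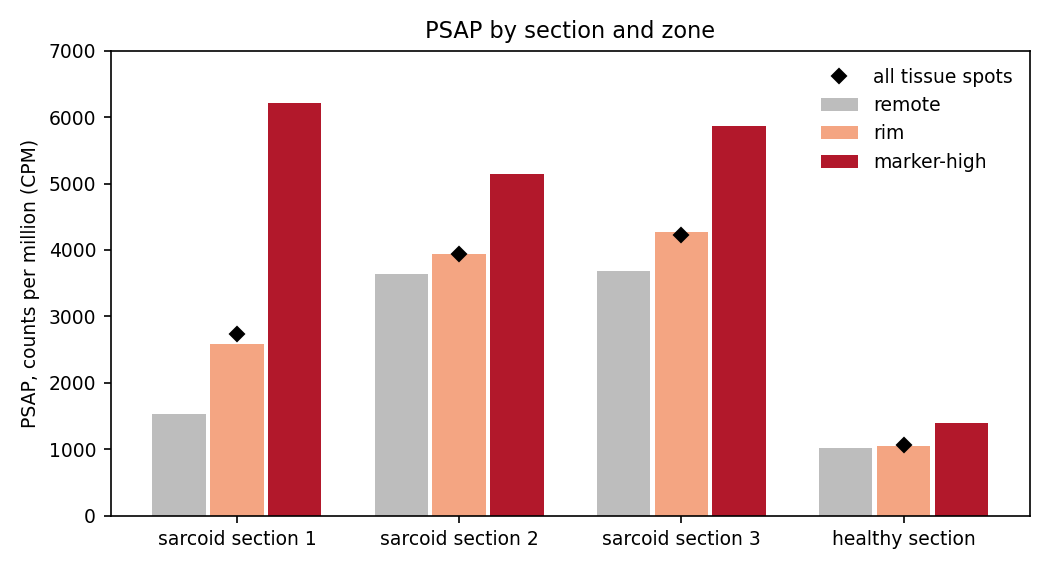
PSAP level in CPM in each section, with bars for the remote, rim and marker-high zones and diamonds for all tissue spots of the section. The marker-high bars stand at 6210, 5147 and 5870 CPM in the sarcoid sections and at 1393 CPM in the healthy section; each bar is a single sum over spots and has no error bar.

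Within the sarcoid sections, genes of the macrophage, lysosome and glycolysis lists rose in spots rich in the granuloma macrophage score genes, and genes of the alveolar type 2, secretory airway and blood vessel lists fell (adjusted p = 0.374 with an estimated correlation for each). The spots were chosen in these same data for macrophage transcripts. Rises of other macrophage genes and a lower share of other cell types were therefore partly built in. Leaving the score genes out of the tests does not remove this. PSAP was 5742 ± 543 CPM (SD, n = 3) in the marker-high zones and 2951 ± 1231 CPM in the remote zones. The log2 fold change was 1.26 ± 0.31 (SE), with an adjusted p of 0.017 in edgeR and an unadjusted p of 0.00313. It was higher in 3 of 3 sarcoid sections, by 4.06-fold, 1.41-fold and 1.59-fold. In the healthy section the same division gave 1393 CPM against 1015 CPM, a ratio of 1.37 with no replicate. The difference between the sarcoid and healthy zone effects was 0.80 ± 0.62 on the log2 scale (unadjusted p = 0.23).

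The metallothionein genes MT1H and MT1G, whose products bind zinc and copper, had the largest rises (log2 fold changes 3.44 ± 0.35 and 3.07 ± 0.35). The nucleoside transporter SLC28A3 rose by 2.92 ± 0.33, cytidine deaminase CDA by 2.84 ± 0.40, the antimicrobial peptide gene CAMP by 2.78 ± 0.47, C15orf48 by 2.69 ± 0.41 and the decoy interleukin-1 receptor IL1R2 by 2.48 ± 0.36. TM4SF19, FAIM2 and EGLN3, a prolyl hydroxylase, rose by 2.50, 2.46 and 2.45. Airway secretory and ciliary genes led the falls, with MUC5B at 14 ± 11 against 494 ± 552 CPM (-4.49 ± 0.47) and BPIFB1, SCGB1A1, SCGB3A1, PROM1 and FAM3D between -3.56 and -3.86. The level of MUC5B came mostly from sarcoid sections 1 and 3, at 23.2 against 1094 and 16.9 against 382 CPM, while section 2 held 1.83 against 6.93 CPM, and BPIFB1 had 0 UMIs in the marker-high zone of section 2 and 0.0779 CPM in its remote zone. The ciliary dynein gene DNAH9 had 3 UMIs in the 3 marker-high zones together (0.572 CPM of their pooled UMIs), against a mean of 20.2 CPM in the remote zones. SLC6A4 and the angiotensin receptor gene AGTR2 fell as well (-3.82 and -3.66). WDR38 had 0 UMIs in the 3 marker-high zones together, against a mean of 22.2 CPM in the remote zones. Overall counts were 1762 genes higher and 2047 lower among 12015 tested.

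Of 14 general macrophage genes 9 rose over all genes and 10 adjusted over the list alone, with FCER1G at 877 ± 65.7 against 351 ± 153 CPM (1.61 ± 0.27) and the endotoxin co-receptor CD14 at 530 ± 90.3 against 220 ± 75.3 CPM (1.52 ± 0.26). The lysozyme gene LYZ, singled out after its values were seen, was the most abundant of them and did not pass (0.78 ± 0.45, adjusted p = 0.219, and 1.51 with an adjusted p of 0.000255 without sarcoid section 1). It stood at 17657 CPM in the marker-high and 33149 CPM in the remote zone of section 1, so the summed list was lower in the marker-high zone there (26155 against 35247 CPM), although 13 of the 14 genes were higher, and higher in sections 2 and 3 by 1.77-fold and 2.13-fold. Without LYZ the sum was higher in all 3 sections, by 4.05-fold, 1.38-fold and 1.45-fold. The alveolar macrophage list split: FBP1 and INHBA rose (2.35 ± 0.29 and 1.66 ± 0.21), while FABP4 and MCEMP1 fell (-2.33 ± 0.29 and -1.74 ± 0.32), and 3 genes passed in each direction over all genes, 5 up and 4 down adjusted over the list alone. Lysosomal genes rose in 21 of 29, over all genes and adjusted over the list alone. These included the cysteine protease CTSK (2.27 ± 0.34) and the lysosomal membrane protein LAMP2 (0.76 ± 0.12). Of the genes that sort or bind prosaposin, M6PR, IGF2R and LRP1 rose (0.95, 0.88 and 0.65), and SORT1 stood at 0.32 ± 0.13 (adjusted p = 0.0981), with 4 of 4 passing adjusted over the list alone. In the lipid-handling list 4 genes rose, including APOE (1.44 ± 0.42), and CD36 fell (-1.91 ± 0.32), against 5 up and 1 down adjusted over the list alone. With an estimated correlation the general macrophage, lysosome and prosaposin sorting lists each had an adjusted p = 0.374.

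In the interferon-gamma response list 12 of 16 genes rose over all genes and 13 adjusted over the list alone, with CXCL9 at 478 ± 217 against 187 ± 104 CPM (1.61 ± 0.21). HLA-DRA was 1 of 8 MHC class II genes of 10 that rose (1.33 ± 0.31), with 10 adjusted over the list alone. TNF (1.65 ± 0.22) and IL1B (1.85 ± 0.38) were among 6 of 11 genes of TNF and interleukin-1 signalling, with 6 adjusted over the list alone. Of 8 glycolysis and mTORC1 genes 7 rose over all genes, and 7 were higher and 1 lower adjusted over the list alone, including HK2 (1.67 ± 0.22) and the glucose transporter SLC2A1 (1.25 ± 0.17). CD4, TRAC and 4 other T cell genes of 12 rose (8 adjusted over the list alone), IFNG was 1 of 3 activation genes of 12 that rose (1.91 ± 0.37, with 4 adjusted over the list alone), and RRM2 and MKI67 were among 4 of 9 cell cycle genes (6 adjusted over the list alone). Of 16 fibroblast and matrix genes 10 rose, over all genes and adjusted over the list alone, including TIMP1 (1.60 ± 0.28), COL6A3 (0.89 ± 0.20) and CTHRC1 (1.14 ± 0.26).

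All 9 alveolar type 2 genes fell over all genes and adjusted over the list alone, including LPCAT1, a surfactant lipid acyltransferase (139 ± 64.6 against 513 ± 138 CPM, -1.81 ± 0.33). Of 8 alveolar type 1 genes 7 fell, with AGER at 136 ± 70.8 against 928 ± 500 CPM, and PDPN rose (1.21 ± 0.16). Adjusted over the list alone, 7 were again lower and 1 higher. Secretory airway genes fell in 8 of 9 (9 adjusted over the list alone), and blood vessel genes in 11 of 12 (11), with CDH5, the endothelial cadherin gene, at 29.7 ± 19 against 193 ± 98.6 CPM (-2.41 ± 0.34). JCHAIN, IGHA1 and SDC1 were among 6 of 9 plasma cell genes that fell (7 adjusted over the list alone), and KIT and CPA3 among 5 of 6 mast cell genes (5). Of 8 ciliated and 8 smooth muscle genes 4 and 5 fell (7 and 6 adjusted over the list alone), and 2 of 2 erythrocyte and 2 of 2 mesothelial genes, and haemoglobin HBA1 fell by 2.35 on the log2 scale. Camera did not call the alveolar macrophage list (adjusted p = 0.381) or the lipid-handling list (adjusted p = 0.437). The lists of B cells, lymphoid follicles, neutrophils, gland and cartilage, lymphatic vessels, complement, vitamin D, hypoxia and immediate-early genes were not called by camera either. Of all these lists fry called the hypoxia list (adjusted p = 0.0367). Of the lists that camera called, fry did not call the ciliated list (adjusted p = 0.103) or the alveolar type 1 list (adjusted p = 0.0649). Over all genes, 2 of 5 lymphoid follicle, 2 of 4 neutrophil, 2 of 6 hypoxia and 1 of 3 vitamin D genes rose, 1 of 6 B cell, 2 of 4 gland and cartilage, 2 of 9 complement and 2 of 11 immediate-early genes fell, and 1 of 5 lymphatic genes rose and 3 fell. Of all 12015 genes tested 1762 rose and 2047 fell, so falls in 1 of 6 or 2 of 11 genes were near the share of any gene. Adjusted over the list alone, 2 lymphoid follicle, 2 hypoxia and 1 vitamin D genes were higher, 2 gland and cartilage genes were lower, 0 B cell and 0 immediate-early genes passed, and the neutrophil, complement and lymphatic lists had 3, 2 and 1 higher and 1, 3 and 3 lower.

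With the preset correlation camera called 19 lists, and fry called 18, of which 17 were among the 19. With an estimated correlation 0 were called, with an adjusted p of at least 0.374 for each. Marker-high spots also held more UMIs than remote spots, with medians of 18773 against 4680.5, 16544 against 9980.5 and 10736 against 3954 in the sarcoid sections. The gene count was 1874 with every spot thinned before scoring, 1634 without the section block, 2481 with DESeq2 and 2 without sarcoid section 3 (3552 at an unadjusted p under 0.05). The adjusted p of PSAP was 0.122 without sarcoid section 3 and 0.0839 without the block, and its log2 fold change was 0.76 without sarcoid section 1.

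**Figure D2:**
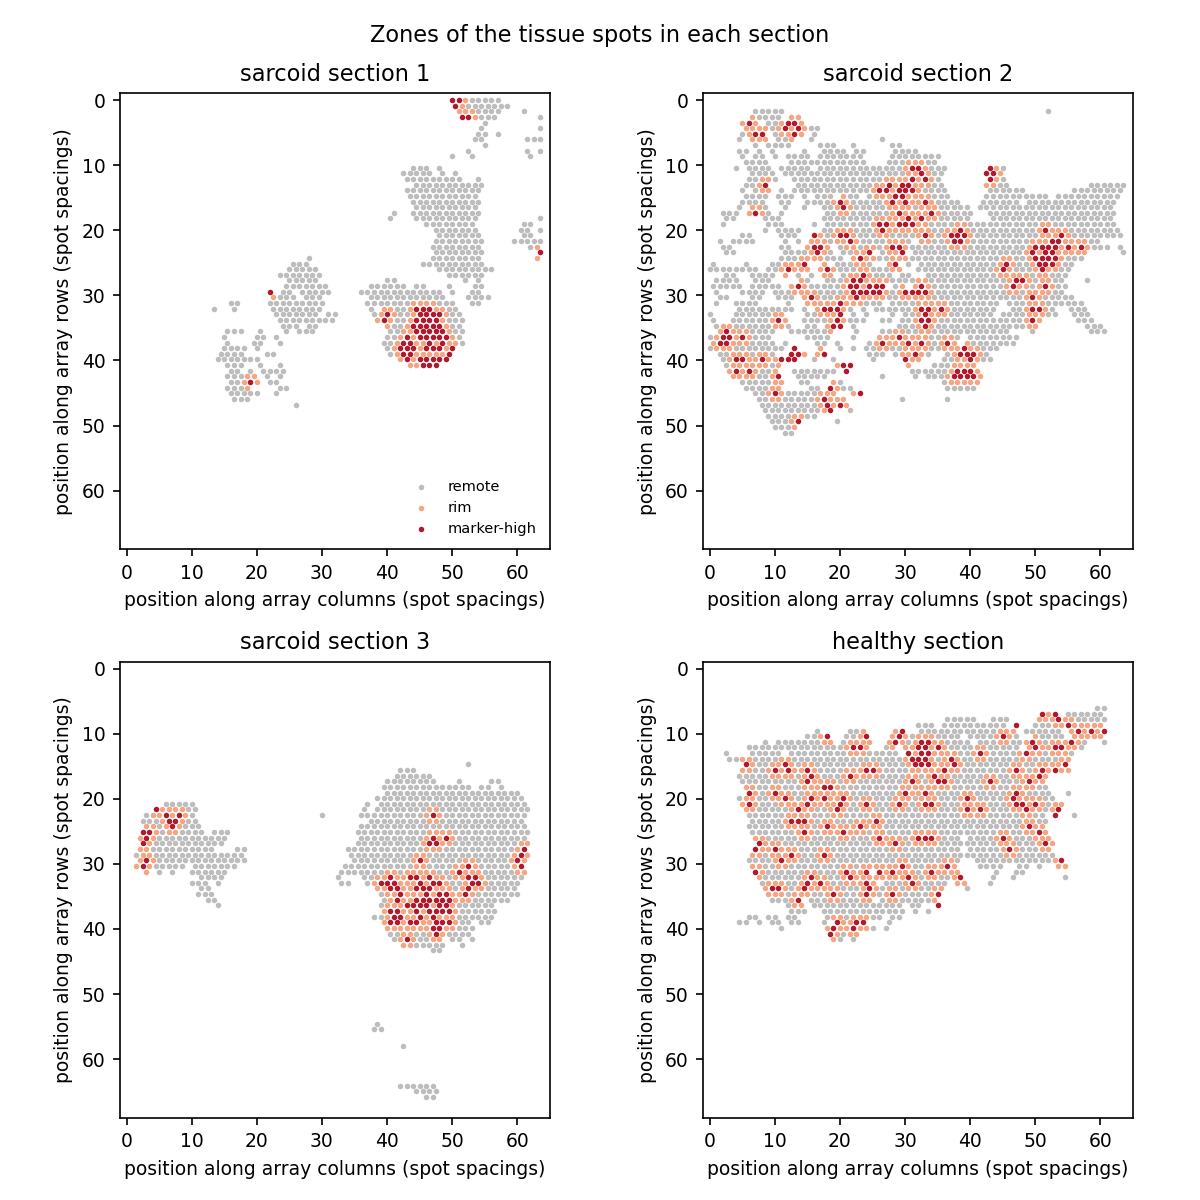
Position of every tissue spot with at least 500 UMIs in each section, in units of the spacing between neighbouring spots, coloured by zone. Of the neighbours of marker-high spots, 61.9%, 34.1% and 40.8% were themselves marker-high in the sarcoid sections and 14.8% in the healthy section, against about 10% when the same number of spots was drawn at random.

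The score itself separated the sections. CHIT1 stood at 2586, 936 and 1967 CPM in the marker-high zones of the sarcoid sections and at 168, 359 and 373 CPM in their remote zones, against 69.1 and 1.56 CPM in the healthy section. SPP1, which encodes osteopontin, stood at 1194, 2022 and 3372 CPM in the marker-high and 50.5, 238 and 488 CPM in the remote zones of the sarcoid sections, against 37.2 and 0 CPM in the healthy section. TREM2 and ACP5 separated the marker-high zones less. TREM2 stood at 152, 179 and 101 CPM in sarcoid against 122 CPM in healthy, and ACP5 at 772, 509 and 451 against 393 CPM. Most healthy marker-high spots were chosen on a single UMI of the score genes, which by itself raises these genes in that zone. Over whole sections TREM2 stood at 66.5, 129 and 88.2 CPM in sarcoid against 18.9 CPM in healthy. ACP5 stood at 346, 398 and 359 CPM against 52.8 CPM. In the healthy section 1184 of 1484 scored spots had a score of 0. Marker-high spots were grouped in space in the sarcoid sections, where their share among neighbours exceeded the highest of 1000 random draws (19.2%, 14.5% and 16.8%). In the healthy section 1 of the 1000 random draws reached the share of 14.8% (highest draw 15.5%), so its marker-high spots also lay together more often than at random, by a smaller margin. These healthy spots were shallower than the remote ones (medians of 1216.5 against 1498 UMIs), the reverse of the sarcoid sections. Of them, 43.2% lay in the healthy cluster with the lowest median, 888 UMIs. A spot with a single score UMI scores higher the fewer UMIs it holds. The healthy grouping may thus reflect depth, which was not tested.

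Between rim spots, which border the marker-high spots, and remote spots, no single gene passed over all genes. CCL19 was 634 ± 168 CPM in the rims and 263 ± 130 CPM in the remote zones (log2 fold change 1.35 ± 0.27, adjusted p = 0.248), and 488 ± 219 CPM in the marker-high zones. The matrix genes THBS2, CTHRC1 and TIMP1 had log2 fold changes of 1.08, 1.26 and 1.14, and AGER, a marker of alveolar type 1 cells, of -1.85 ± 0.50 (adjusted p = 0.248 for each). PSAP was 3599 ± 890 CPM in the rims (0.36 ± 0.30, unadjusted p = 0.271), and marker-high spots exceeded the rim by 0.90 ± 0.31 (unadjusted p = 0.0172, adjusted p = 0.133). That last difference did not pass after adjustment in any alternative, and its lowest adjusted p was 0.0504, with DESeq2. In 4 alternatives its unadjusted p was not under 0.05 either: it was 1.07 without sarcoid section 3 (unadjusted p = 0.0681), 0.62 with spots thinned before scoring (unadjusted p = 0.0861), 0.75 with the highest 5% of spots as marker-high (unadjusted p = 0.0522) and 0.83 without the section block (unadjusted p = 0.062). edgeR called 0 of 12015 genes between rim and remote, with 1729 at an unadjusted p under 0.05, DESeq2 called 50 and edgeR without sarcoid section 1 called 309, with CCL19, THBS2, CTHRC1, TIMP1 and AGER passing in both of these fits.

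Adjusted over the list alone, 11 of 16 fibroblast and matrix genes, 8 of 16 interferon-gamma response genes, 6 of 12 T cell genes and 3 of 5 lymphoid follicle genes were higher in the rim, while 9 of 9 alveolar type 2, 7 of 8 alveolar type 1 (the other higher) and 9 of 12 blood vessel genes were lower. Lower too were 3 of 12 lipid-handling, 2 of 6 mast cell, 2 of 9 secretory airway, 2 of 2 mesothelial and 2 of 2 erythrocyte genes, while 1 of 5 lymphatic and 1 of 6 hypoxia genes were higher. Of 10 alveolar macrophage genes 2 were higher and 3 lower, of 9 complement genes 2 and 1, and of the other tested lists 0 genes passed. Over all genes 0 of each passed. Rim spots border spots chosen in these same data for macrophage transcripts, so part of these differences may be built in. They also held more UMIs than remote spots, with medians of 10274 against 4680.5, 14478 against 9980.5 and 6945 against 3954 in the sarcoid sections. Camera called 17 lists with the preset correlation, 0 with an estimated one (adjusted p of at least 0.355 for each) and 0 with fry. Between marker-high and rim zones edgeR called 0 genes (2835 at an unadjusted p under 0.05), and DESeq2 called 341. This 0 was not stable within edgeR, which called 251 genes without the expression filter, 681 without sarcoid section 1, 1021 with a rim of 2 rings, 1281 with the zone from clustering and 1372 with the highest 20% of spots as marker-high. Between the sarcoid and healthy zone effects edgeR called 0 of 12015 genes (1252 at an unadjusted p under 0.05), DESeq2 called 23, and edgeR without sarcoid section 1 called 80.

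**Figure D3:**
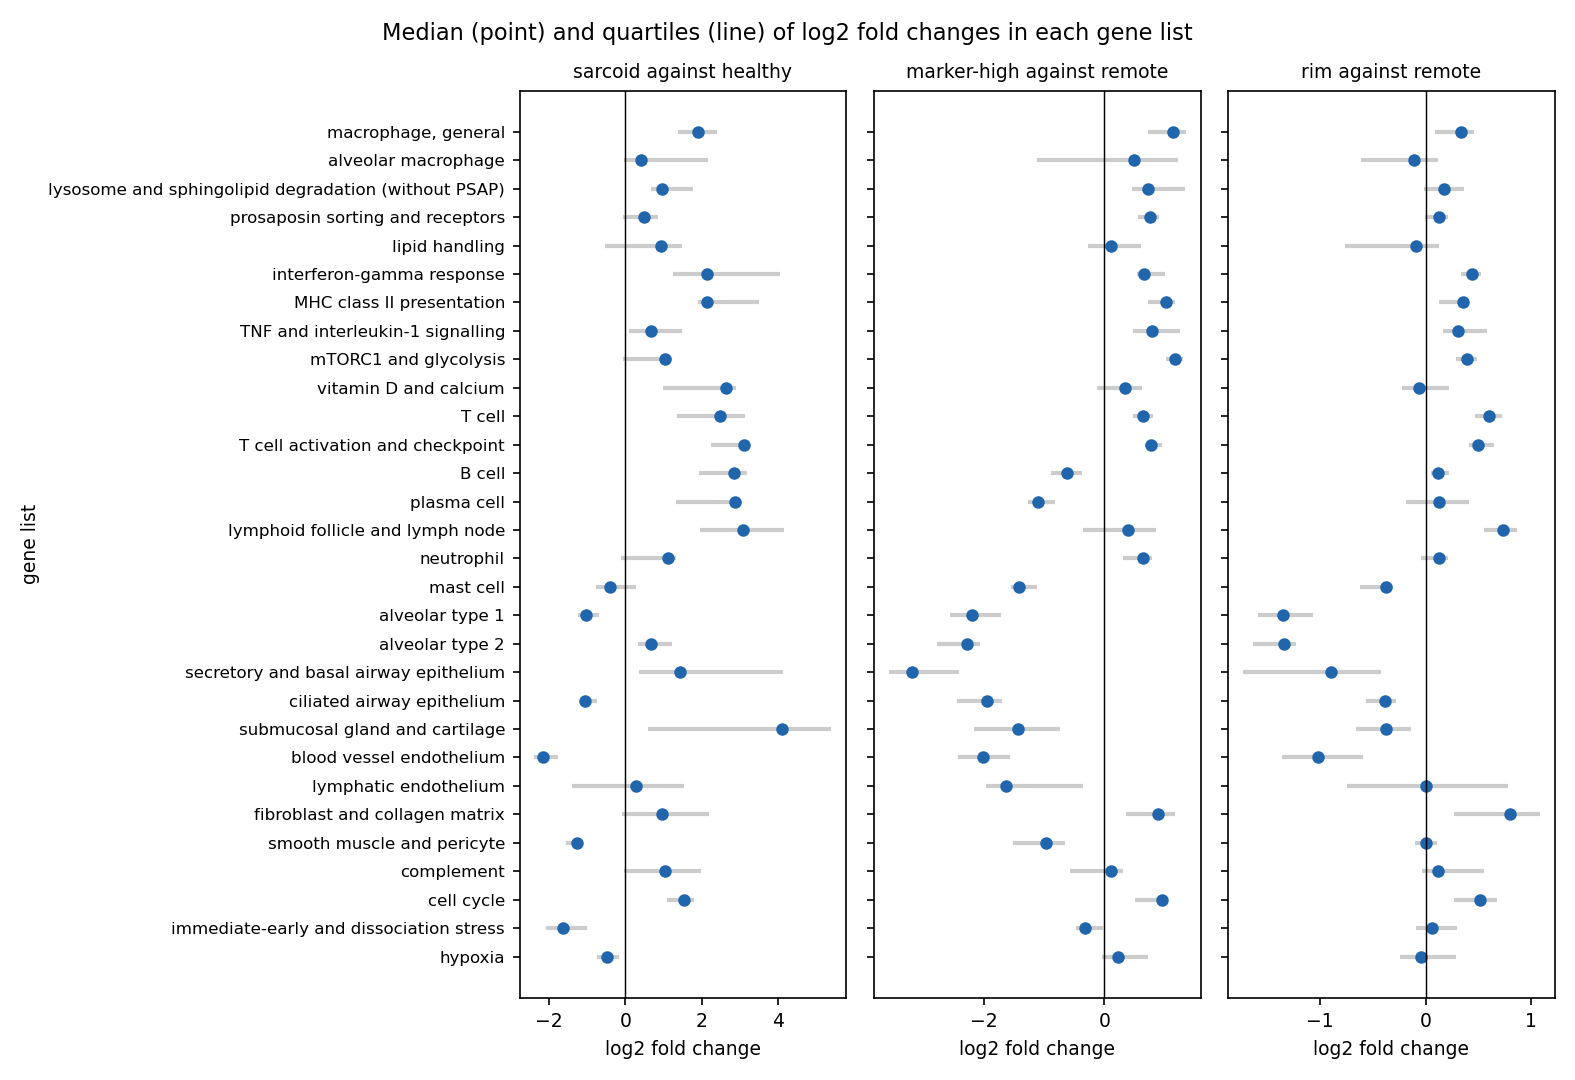
Median (point) and quartiles (line) of the log2 fold changes of the tested members of each gene list with at least 3 members, for sarcoid against healthy sections, marker-high against remote zones and rim against remote zones, each panel on its own scale. Genes with 0 healthy UMIs stand at their bound in the first panel. The medians of the fibroblast and matrix list were 0.97, 0.90 and 0.80 and those of the blood vessel list -2.16, -2.02 and -1.02.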

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

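The fits with thinned sections, with spots thinned before scoring and without sarcoid section 1 were planned, while their use to weigh explanations, the list test of the difference in zone effects, the counts of score UMIs, the macrophage list values, the remote zones alone and the sections set alone were chosen after the zone results were seen. The list test compared the marker-high against remote difference of the sarcoid sections with that of the healthy section and marked 10 lists with the preset correlation, none of them with an estimated correlation (adjusted p of at least 0.54) or with fry (adjusted p of at least 0.666). As median log2 differences, sarcoid minus healthy, these were 0.55 for lysosome genes, 1.07 for mTORC1 and glycolysis, 0.47 for fibroblast and matrix, -0.75 for plasma cells, -1.61 for mast cells, -2.13 for alveolar type 1, -2.56 for alveolar type 2, -2.08 for secretory airway epithelium, -1.98 for blood vessel endothelium and -1.06 for smooth muscle and pericytes. The adjusted p with the preset correlation lay between 4.63e-10 and 0.024 for these lists.

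In the healthy section itself the median marker-high against remote differences of these lists were 0.26 for lysosome genes, 0.20 for mTORC1 and glycolysis, 0.09 for fibroblast and matrix, 0.47 for plasma cells, 0.19 for mast cells, 0.02 for alveolar type 1, -0.09 for alveolar type 2, -0.98 for secretory airway epithelium, -0.02 for vessels and -0.04 for smooth muscle. These medians come from 1 section and were not tested, and between the same zones edgeR called 0 of 12015 genes (455 at an unadjusted p under 0.05). A marker-high spot of the healthy section held a median of 1 UMI of the score genes, against 190, 136.5 and 102.5 in the sarcoid sections, and 103 of its 148 marker-high spots held a single one. A zone resting on very few UMIs in the healthy section is a candidate explanation (median 1), because spots chosen on single molecules may differ less from their surroundings whatever the tissue holds. A biological difference, such as granulomas in sarcoid lung and none in healthy lung, stays open and was not tested, since the same spots carry both.

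PSAP rose in marker-high spots, and these also held more UMIs. With every spot thinned to 500 UMIs before scoring, the log2 difference was 1.21 ± 0.33, which argues against depth at scoring as the whole cause, and without sarcoid section 1, where the difference was largest, it was 0.76 ± 0.16 (unadjusted p = 0.000436), which argues against a single section as the whole cause. As CPM ratios without TMM factors, sections 2 and 3 stood at 1.41 and 1.59, near the 1.37 of the healthy section. A rise beyond that of the healthy section thus rests mostly on section 1. The larger ratio of section 1 went with a low remote level, 1530 CPM against 3644 and 3681 CPM in sections 2 and 3. The marker-high levels were closer to each other, at 6210, 5147 and 5870 CPM. Whether the tissue making up the remote zone of section 1 accounts for its ratio was not tested. A general enrichment of PSAP in macrophages could account for part of the rise: away from both the marker-high and rim zones, the 10% of remote spots highest in the alveolar macrophage list held 1.92, 1.3 and 1.77 times the PSAP share of other remote spots in the sarcoid sections, and 1.21 times in the healthy section. The summed general macrophage list in the marker-high zones was 0.74, 1.77 and 2.13 times its remote level in sarcoid sections 1 to 3, but LYZ, a gene also on the gland list, made up 33149 of the 35247 CPM in the remote zone of section 1, and without LYZ, left out after its values were seen, the list was 4.05, 1.38 and 1.45 times its remote level, beside 4.06, 1.41 and 1.59 times for PSAP, and in the healthy section 1.73 times beside 1.37 times. Whether PSAP per macrophage differs between the zones was not measured, because a spot mixes cells.

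The genes called between sarcoid and healthy sections were also weighed against depth and zone content. Thinning every section to the total of the shallowest left 98.5% of the 404 genes called in the same direction. Thinning keeps each gene's expected share of a section's UMIs, so it covers unequal totals only. It cannot decide whether lower capture or RNA quality in the healthy section caused calls. In the remote zones alone 100% of the 404 genes kept their direction, with a median shift of 1.97 against 2.30 over all spots. There edgeR called 0 genes (2066 at an unadjusted p under 0.05), and the spread between sections was wider for PSAP (SE 0.81 against 0.57). The genes were chosen on sums that include the remote spots, so keeping their direction was partly fixed in advance. The remote zones also held score gene transcripts, with CHIT1 at 168, 359 and 373 CPM in sarcoid against 1.56 CPM in healthy. These values therefore cannot decide whether granuloma content accounts for the called genes. With each section set alone in turn, the healthy section gave 404 genes in edgeR and the highest of the others 0 (at most 581 at an unadjusted p under 0.05), and 1 of the 4 splits gave as many as the real one, which is too few splits for a share under 0.05. Differences between individuals, sampling site and handling of the single healthy section stay open, as they cannot be told apart from disease with 1 healthy section.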

How the results depend on the processing

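Except for the remote zone alone, the sarcoid sections alone, RLE factors for the zone lists and all alternatives for marker-high against rim zones, which were added after seeing the data, the alternatives were planned. No paired analysis was possible because there is 1 healthy section, and no label ties it to a sarcoid section. The zone fits keep the section as a block, and without that replicate block 1634 genes were called in place of 3809 between marker-high and remote zones, while PSAP had a log2 difference of 1.14 (adjusted p = 0.0839). The cause of each change below was not tested unless named.

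Between sarcoid and healthy sections, 404 genes became 1674 with DESeq2, 740 without a filter, 794 after thinning and 0 in the remote zones alone, and ranged from 0 to 700 when each sarcoid section was left out. The share higher was 55.2% and with equal spot weights 67.2% (531 genes). PSAP kept its direction throughout, between 1.70 and 2.06 with a section left out and at 1.57 in the remote zones alone. Its unadjusted p was no longer under 0.05 without section 2 (unadjusted p = 0.0757), without section 3 (unadjusted p = 0.0905) or in the remote zones alone (unadjusted p = 0.11). The lists called fell from 21 to 0 with an estimated correlation and to 0 with fry. Between marker-high and remote zones, 3809 genes became 2481 with DESeq2 and 1874 with spots thinned before scoring, and ranged from 2 to 3032 with a section left out, while PSAP ranged from 0.76 to 1.63. The 19 lists called became 0 with an estimated correlation. Between rim and remote zones, 0 genes became 50 with DESeq2 and 3 without a filter, and ranged from 0 to 309 with a section left out. The 17 lists called became 0 with an estimated correlation and 0 with fry. Between marker-high and rim zones, 0 genes became 341 with DESeq2, 251 without a filter, 1 with the highest 5% and 1372 with the highest 20% of spots, 1021 with 2 rings, 1281 with the zone from clustering and 9 in the sarcoid sections alone, and ranged from 0 to 681 with a section left out. For the difference of zone effects, 0 genes became 23 with DESeq2 and ranged from 0 to 80 with a section left out.

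In the comparisons of sections and of marker-high and rim against remote zones, no gene named there and no list called by camera changed direction under an alternative it was tested in. Of 470 pairs of a named gene and an alternative in the section comparison, 352 kept their side of the threshold, 106 lost the call and 12 gained it, and of 1001 such pairs for marker-high against remote zones 889, 108 and 4 did. Without sarcoid section 3, 60 of 62 named genes lost the call for marker-high against remote zones. In the section comparison 43 of 47 lost it without section 3, and 43 of 47 in the remote zones alone. For rim against remote zones 132 of 150 pairs kept their side and 18 gained the call, among them 9 of 10 genes with DESeq2 and 8 of 10 without sarcoid section 1. The result for PSAP in the section comparison rests on 4 sections, of which the healthy one has the lowest total, 2330755 UMIs, and this depth limits genes under about 10 UMIs there.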

Other observations

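The values of this part were chosen after the zone results were seen, and no test was run on them in this part. Sections were clustered without the score genes and each cluster is named by its leading genes. In sarcoid section 3, a region of 44 spots led by FABP4, RBP4 and MCEMP1, genes of alveolar macrophages, held 8275 CPM of PSAP, above the 5717 CPM of its region led by MT1H and SPP1 (58 spots). In section 2 the highest level was 5936 CPM, in a region of 185 spots led by CHIT1, DNASE2B and TFRC. The next was 4406 CPM, in a region of 119 spots led by MMP11, ASPN and LRRC17. Regions led by SPP1 and CAMP (34 spots) and by MT1H, MT1G and SPP1 (213 spots) held 4394 and 4062 CPM. One of 375 spots led by PLA2G4F and FABP4 held 3980 CPM. In section 1 the region led by SPP1 and MT1G held 6421 CPM (48 spots), while a region led by MCEMP1 and FABP4 held 2567 CPM (136 spots), under the 2765 CPM of all its other spots. These are values of single regions, with no replicate and no test between them.

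Genes of the alveolar macrophage list did not share a direction between the zones. FABP4, a lipid-binding protein gene of alveolar macrophages, stood at 441, 221 and 324 CPM in the remote spots highest in that list, at 54.3, 51.2 and 37.8 CPM in the other remote spots and at 6.49, 18 and 11.3 CPM in the marker-high zones of the same sections. MARCO, a scavenger receptor gene of the same list singled out after its values were seen, stood at 665, 623 and 1050 CPM in the remote spots highest in the list and at 65.4, 265 and 265 CPM in the other remote spots, with 416, 454 and 618 CPM in the marker-high zones between them. The list score selected these spots, so the levels of its own genes describe them and test nothing.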
